A study of Caenorhabditis elegans with 2 samples.

How the data were processed

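The data were lists of binding sites from chromatin immunoprecipitation followed by sequencing (ChIP-seq) in mixed-stage embryos of Caenorhabditis elegans. Per the labels, the strain carried an integrated copy of ces-1 tagged with TY1, EGFP and FLAG in an unc-119 mutant background, the tissue was the whole organism, and 2 biological replicates were made with a size range of 150 to 350. Both replicates formed the single group, so no treated or mutant group entered any comparison. The antibody field of the labels names only the target. No control list was analysed here.

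The peak lists were used as deposited, on both ce10 and ce11 coordinates. Per the notes deposited with the libraries, the authors made a relaxed list of 30000 peaks for each replicate and another of 30000 for the pooled replicates against a control, then kept the pooled peaks that passed an irreproducible discovery rate (IDR) step, which compares peak ranks between replicates. The aligner, the peak caller and their versions are not given in the sources used here. The signal of each peak is the peak caller's own value as deposited by the authors, and its scale is not stated. It served within a list to rank peaks, to describe them and to compare peaks with and without a motif. Between builds it served to match the same peak, and between the replicates to compare signal at shared peaks. The deposited −log10 q of each peak was used only to count peaks at or above 2. The deposited lists hold no IDR value per peak. The 6290 peaks of the thresholded ce11 list were exactly the 6290 strongest of the pooled relaxed list by signal.

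Positions are given on ce11, counted from 1, and the ce11 lists alone were placed on genes, with the WBcel235 gene annotation of Ensembl release 115 and the matching reference sequence. No coordinate was converted between builds. Of the 6290 thresholded peaks, 6273 lay on the 6 nuclear chromosomes and entered the analyses, and 17 on the mitochondrial genome were set apart. A summit was placed in a promoter when it lay from 1000 bp upstream to 200 bp downstream of an annotated 5′ end of a protein-coding transcript. Summits were otherwise placed, in this order, in coding exons, untranslated exons, introns or intergenic sequence of protein-coding genes.

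Summits in different lists were matched when they lay within 100 bp. Overlap and promoter shares were compared with 1000 circular shifts of the summits within each chromosome, with a one-sided permutation p; 100 shifts were used for the other locations. Chromosome counts were tested with a two-sided exact binomial test against chromosome length. The Snail-type E-box CAGGTG, or its reverse CACCTG, was sought within 50 bp of each summit and in windows of the same length centred 500 bp to either side, with an exact two-sided McNemar test against the flank with more. The medians of signal with and without the motif were compared by a two-sided permutation test with 100000 resamples. Gene lists were tested with Fisher's exact test, two-sided, against all other protein-coding genes, and microRNA genes against other non-coding genes apart from pseudogenes. Families of tests were adjusted by the Benjamini-Hochberg method, and the threshold was 0.05. Intervals of shares are exact 95% binomial intervals and cover counting error only. Neighbouring genes can share a peak, so the tests treat as independent some genes and peaks that are not.

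The groups, tests, alternatives, 16 gene lists and the rule for named genes were fixed before the data were examined. The rule names protein-coding genes whose 5′ end lies nearest to, and within 1000 bp of, one of the 20 strongest peaks, up to 4 occupied members with the strongest peaks in each list, and ces-1, ces-2, egl-1, hlh-2, hlh-3, dnj-11, pig-1, cdc-25.2, scrt-1, snai-1, unc-119 and hmr-1 whatever their values. Across the lists, 4 entries had no match in the annotation, and the name pattern for chemoreceptors also took in 6 srp genes, 2 src genes and 1 srf gene. Alternatives covered other summit distances, stricter peak sets, each replicate alone, other promoter and motif windows, other backgrounds and the ce10 lists.

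The tests of overlap, promoter share, X share, motif frequency, signal difference and gene lists were checked on simulated data. Planted values of 48.4% for promoter share, 60.7% for overlap, 25% for X share and 12.0% for motif frequency came out as 48.7%, 60.8%, 25.04% and 12.0%. A gene list planted at 60% came out at 59.2% on average over 20 runs. The signal difference was the least precise: a planted 60.5 came out as 46.2 in a single run, and over 20 further runs a planted mean of 60.8 came out as 64.7 on average, between 45.2 and 87.8. Of 20 sets with no planted effect, 1 passed the promoter test, 0 the X test, 0 the motif test and 2 the signal test, and 1 of 300 tests of random gene lists passed. The simulated summits and occupied genes were drawn independently of one another. They lack the clustering and shared peaks of the real lists, so the rate of false calls may be higher there. The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Read depth is unknown here, since the lists hold no read counts; the replicate lists held 6124 and 8283 peaks with a −log10 q of at least 2. With 2 replicates of 1 group, the spread between them describes these libraries and supports no test between conditions.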

Results

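Binding sites of eGFP-tagged CES-1, a zinc finger transcription factor of the Snail family, were mapped by ChIP-seq in mixed-stage embryos of C. elegans. In this animal ces-1 is known for its role in the survival and division of cells in the lineage of the NSM neurons of the pharynx. The data comprised 2 biological replicates of the same strain, with relaxed peak lists of 30000 peaks each, and a pooled list thresholded by IDR that held 6290 peaks. The median width was 390 bp in the pooled list and 384 bp in each replicate. The signal of the thresholded peaks ran from 58.7 to 3177 around a median of 119.3, in the units of the authors' peak caller. Because the tagged factor is named by the labels alone, the peaks are described below as those of the libraries labelled eGFP-CES-1.

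The strongest peaks in both replicates lay at unc-42, which encodes a paired-class homeodomain factor of neurons. The gene lies on the minus strand of chromosome V, from 9764534 to 9769391, and 10 thresholded peaks fell between 9763802 and 9772311. The strongest peak of the whole list (9765383 to 9766138, summit 9765819, signal 3177) lay in an intron, 829 bp upstream of an annotated 5′ end inside the gene. The next (9768698 to 9769980, summit 9769632, signal 2952) was intergenic, 241 bp upstream of a 5′ end, and peaks ranked 4 and 20 at the locus had signals of 1566 and 1112, both in introns. The first 2 of these peaks also held the first 2 ranks in each replicate, with signals of 1444 and 1530 in replicate 1 and 1769 and 1445 in replicate 2. The strongest peak elsewhere had a signal of 1863, so that the top unc-42 peak stood 1.70 times above it, a log2 difference of 0.77, against a single-signal SD of 0.40 on the log2 scale between the replicates over all peaks found in both. That SD is for 1 replicate and for peaks of all strengths, while the signals compared are pooled and strong, so it is a rough guide only. The SD of the log2 ratio between replicates was 0.31 in the strongest 20% of peaks and 0.57 over all.

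**Figure D1:**
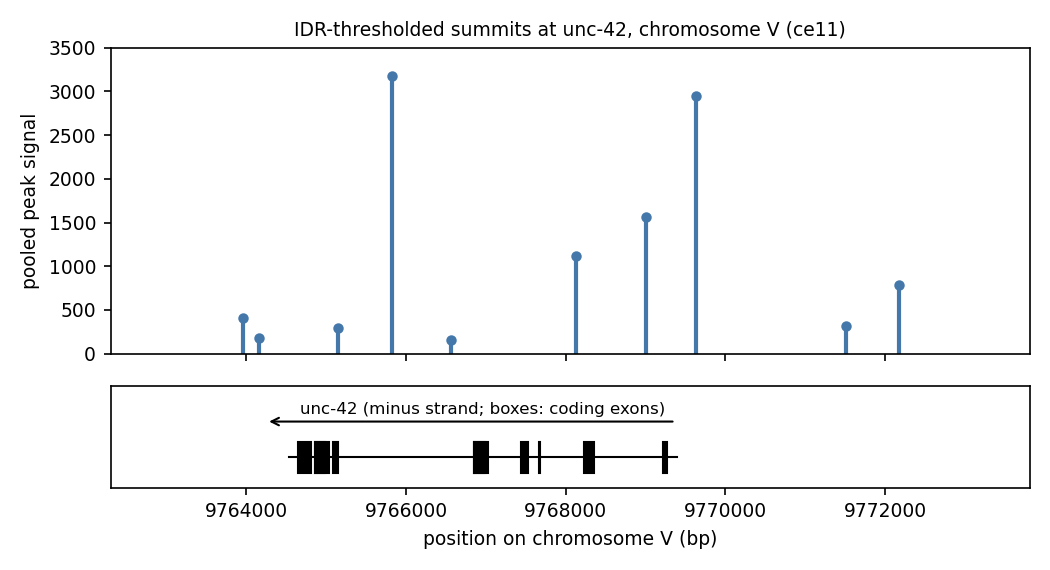
Map of unc-42 on chromosome V (ce11). Horizontal axis, position in bp; vertical axis, signal of each pooled IDR-thresholded peak at its summit, as a dot on a line from 0; boxes are coding exons and the arrow gives the direction of transcription. The 2 highest summits, at 3177 and 2952, lie in an intron and upstream of the gene.

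That strongest peak elsewhere lay 51 bp upstream of C37A2.8 on chromosome I (6799406 to 6799904) and ranked 3 in the pooled list and in both replicates. A further 4 genes had a 5′ end nearest to, and within 1 kb of, a peak among the 20 strongest. The signal was 1263 at egg-5 (I, 4171947 to 4172629), a gene of the oocyte-to-embryo transition, 1170 near ZK1248.17 (II, 5844585 to 5845191), 1159 at fic-1 (IV, 10936851 to 10937276) and 1139 at mrck-1 (V, 6267428 to 6267802), which encodes a kinase of the actomyosin pathway. These 4 peaks were intergenic, and the summit near ZK1248.17 lay 408 bp past the 3′ end of that gene, outside its promoter window. Of the 20 strongest peaks, 12 were intergenic and 8 intronic, 9 lay within 1 kb of a protein-coding 5′ end, 6 were on X, and 0 had CAGGTG within 50 bp of the summit.

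The genes tied to ces-1 by earlier genetics were examined one by one. No summit lay in the promoter window of ces-1 itself (I, 8633897 to 8636169), of the cell death activator egl-1, of the proneural gene hlh-3 or of the Snail-family relatives scrt-1 and snai-1, even in the relaxed pooled list. The nearest thresholded summit to ces-1 (signal 166, summit 8640335) lay 4166 bp outside the gene. The wider window of 2000 bp upstream to 500 bp downstream held no thresholded summit at ces-1, egl-1, hlh-3, scrt-1 or snai-1. Sites farther outside egl-1, hlh-3, scrt-1 or snai-1 were not sought. Below the IDR threshold, the relaxed pooled list had entries at ces-2, which encodes a bZIP factor upstream of ces-1 (signal 55.2, rank 6592). It also had entries at hlh-2 (48.2, rank 7421), at the phosphatase gene cdc-25.2 (27.2, rank 13076) and at the promoter of unc-119 (57.9, rank 6362). That list of 30000 was deposited as peaks and background. Its median signal was 24.3, and 7013 of its entries had a −log10 q of at least 2, so these entries may be background. By contrast, pig-1, a kinase gene of asymmetric neuroblast divisions, had a thresholded summit 153 bp upstream of a 5′ end (IV, 519502 to 519731, signal 348, rank 520). The chaperone gene dnj-11 had one 254 bp upstream (IV, 6585494 to 6585688, signal 196, rank 1604). Both were intergenic and present in each replicate, with signals of 166 and 179 at pig-1 and 105 and 86.5 at dnj-11.

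The cadherin gene hmr-1, on the minus strand of chromosome I from 11075755 to 11134667, held 11 thresholded summits in its body, all intronic, and 1 in its promoter window, 326 bp upstream of a 5′ end (signal 280). The strongest intronic summit, at 11124874, had a signal of 615 and ranked 138. Among protein-coding genes mpz-1 had more summits in its body, 13, and unc-7 had the same number as hmr-1; both were picked out after the values had been seen. The gene is 58913 bp long and carried 1.87 summits per 10 kb, against 0.626 over the nuclear genome; of the other 19 genes among the 20 with most summits in the body, 18 had a higher density.

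How closely the 2 replicates matched was measured first by position. Of the 6270 strongest nuclear peaks of replicate 1, 4786, or 76.3% (95% interval 75.3 to 77.4), had a summit within 100 bp of one of the 6271 strongest of replicate 2. Shifted summits gave a mean of 1.32% and at most 1.75% (permutation p = 0.001, the smallest that 1000 shifts can give). Of the 6273 thresholded nuclear peaks, 5928, or 94.5%, were found in both relaxed replicate lists and 6 in neither; the thresholded list was itself chosen for such agreement.

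Signal was then compared at the 5928 shared peaks. Across peaks, which are not independent replicates, Spearman's rho was 0.811 and Pearson's r of the log2 signals was 0.82. The log2 ratio of replicate 2 to replicate 1 had an SD of 0.57, and 92.2% of peaks lay within 2-fold of the median ratio. Precision followed signal strength. In the strongest 20% of peaks, 99.0% were found in both replicates and the SD of the log2 ratio was 0.31, and in the weakest 20% these were 87.3% and 0.79.

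**Figure D2:**
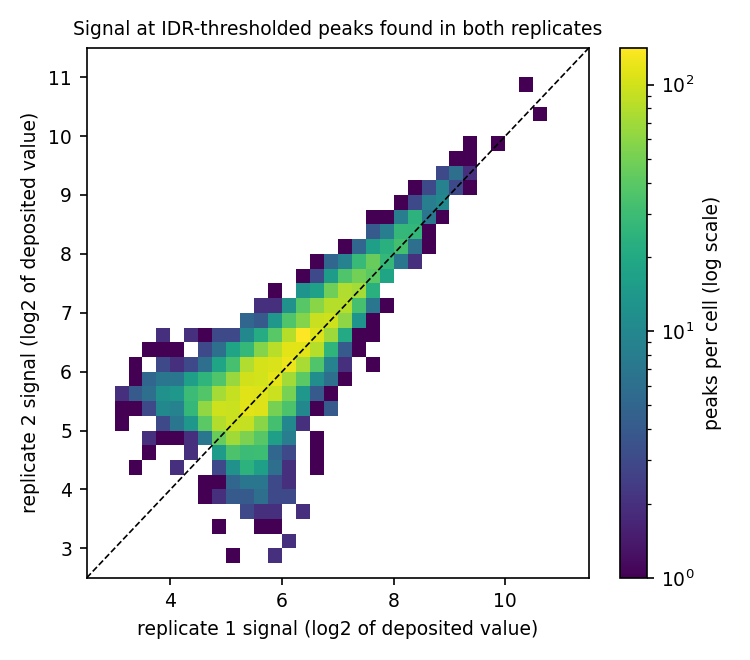
Signal of the 5928 thresholded peaks found in both replicates. Axes, log2 of the deposited signal in replicate 1 and in replicate 2; the colour of each cell gives the number of peaks on a log scale, and the dashed line marks equal signal. Strong peaks lie close to the line and weak peaks spread away from it, with Spearman's rho of 0.811 over all of them.

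The position of the summits relative to genes was then described. Peaks crowded just upstream of genes and were scarce in coding sequence. In all, 2780 of 6273 summits, or 44.3% (95% interval 43.1 to 45.6), lay in a promoter window, against 25.7% for shifted summits, a ratio of 1.72 (permutation p = 0.001, the smallest possible). Summits were most frequent from 100 to 200 bp upstream of the nearest 5′ end, with 623 in that bin against 149 when shifted. Within 1 kb of a 5′ end, 2484 summits were upstream and 633 downstream. Intergenic sequence held 62.7% of summits against 37.2% when shifted, introns 29.3% against 33.6%, untranslated exons 5.47% against 4.93%, and coding exons 2.53% against 24.3%. Over 2 kb from any protein-coding 5′ end lay 31.1% of summits, against 35.5% when shifted. By classes of 20% of peaks, from the strongest to the weakest, the promoter share was 44.8%, 46.1%, 47.9%, 43.5% and 39.3%.

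**Figure D3:**
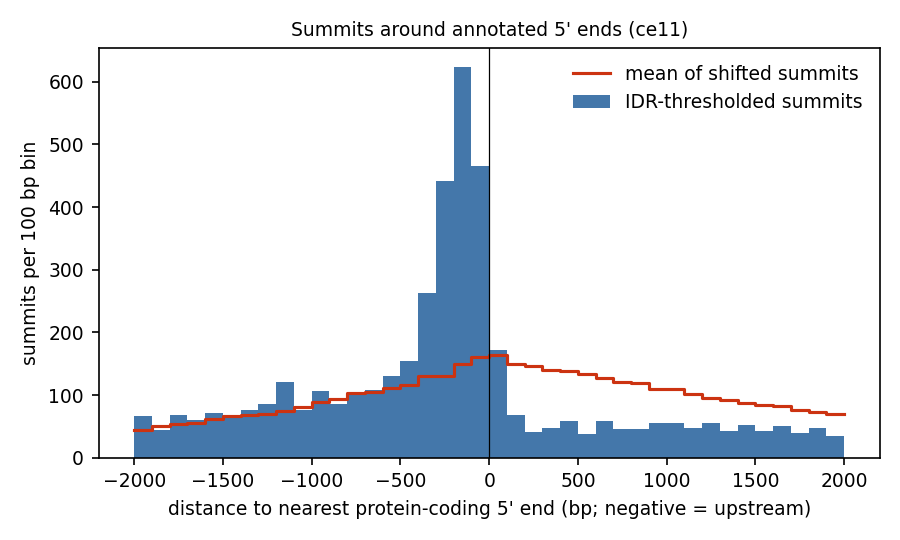
Summits around the nearest protein-coding 5′ end. Horizontal axis, distance in bp, negative upstream; vertical axis, summits per 100 bp bin, as bars for the thresholded peaks and as a line for the mean of shifted summits. The highest bar, 623, covers 100 to 200 bp upstream, where the line is at 149.

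Peaks were spread unevenly over the chromosomes. The X chromosome held 1425 peaks, or 22.7% (95% interval 21.7 to 23.8), with 17.7% of the nuclear length, a ratio of 1.29 (exact binomial p = 3.9e-24). Chromosomes I and III were also above their length, with 1126 and 958 peaks and ratios of 1.19 and 1.11. Chromosome V, with 871 peaks, had a ratio of 0.665, and chromosome IV, with 944, of 0.863. Chromosome II, with 949 peaks, had a ratio of 0.993 (exact binomial p = 0.82), and the other 5 chromosomes passed adjustment over the 6. The test treats peaks as independent although they cluster. Among the 500 strongest peaks the X ratio was 1.18, with an exact binomial p of 0.067.

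Snail-family proteins bind the E-box CAGGTG, so its frequency at summits was compared with that in the flanks of the same peaks. The motif was rarer at summits. It was present within 50 bp of 113 summits, or 1.80% (95% interval 1.49 to 2.16), and in 158 and 151 of the flanking windows, or 2.52% and 2.41%. The difference from the flank with more was −0.717 percentage points (exact McNemar p = 0.0070), and p was 0.020 against the other flank. In the strongest 20% of peaks, 12 summits had the motif against 32 flanks (0.956% against 2.55%, exact McNemar adjusted p = 0.014 over 5 classes; unadjusted exact p = 0.0095 against the other flank). In the weakest 20% the numbers were 28 and 29, and the other 3 classes did not pass adjustment. Whether these classes of 20% differ from one another was not tested. Peaks with the motif had a median signal of 106 and those without 119.5, a difference of −13.2 (permutation p = 0.17), which was not distinguishable from 0; with a window of 25 bp it was 0.19 (permutation p = 0.99).

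**Figure D4:**
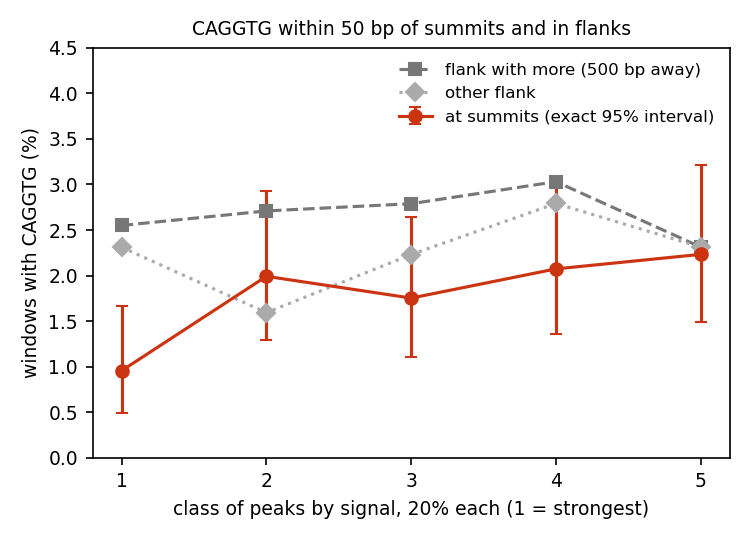
Share of windows with CAGGTG by class of peak signal. Horizontal axis, classes of 20% of peaks from 1 (strongest) to 5 (weakest); vertical axis, percent of windows; circles are summits with exact 95% intervals, squares the flank with more and diamonds the other flank. In the strongest 20% of peaks the summits stand at 0.956% and the higher flank at 2.55%.

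Gene groups fixed in advance were then compared for thresholded summits in the promoter window. Of 19973 protein-coding genes, 3233, or 16.2%, had one. Of the 16 lists, 3 held more occupied genes than the rest, 2 held fewer and 11 did not pass the test, all by Fisher's exact test with Benjamini-Hochberg adjustment. A gene counted as occupied if a summit lay in the window of any of its annotated 5′ ends. The number of 5′ ends and expression in embryos were not adjusted for. The chemoreceptor, collagen, terminal intestine and germline lists were chosen as genes mostly expressed outside early embryonic lineages.

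Genes expressed across the nervous system stood highest. Of 22 pan-neuronal genes 19 were occupied, or 86.4% (95% interval 65.1 to 97.1; adjusted exact p = 4.5e-12). The strongest were the exchange factor gene rgef-1 (V, 9561896 to 9562195, signal 338, 353 bp upstream), the neuropeptide processing gene egl-21 (294, 90 bp upstream), unc-18, which acts in synaptic vesicle release (244), and the kinesin gene unc-104 (186). With only the 500 strongest peaks, 0 of the 22 genes were occupied, where 1.27% of all protein-coding genes were, so that this setting can say little of the list. The 3 members without a thresholded promoter summit included unc-119, which had a summit elsewhere in the gene with a signal of 365.

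Ribosomal protein genes were occupied at 62 of 78, or 79.5% (95% interval 68.8 to 87.8; adjusted exact p = 5.1e-34). The signal reached 1011 at rpl-12 (IV, 13240544 to 13240945, 62 bp upstream, rank 27), 561 at rpl-3, 503 at rpl-20 and 487 at rps-0. Of 45 cell cycle genes 20 were occupied, or 44.4% (95% interval 29.6 to 60; adjusted exact p = 2.9e-05). They included emb-27, a subunit of the anaphase-promoting complex (II, 8162252 to 8162559, signal 563), the E2F gene efl-1 (459), lin-23, which encodes an F-box protein that restrains division (442), and fzy-1, an activator of the anaphase-promoting complex (303). Where each peak was given only to the gene with the nearest 5′ end, 30 ribosomal protein genes, 15 pan-neuronal genes and 12 cell cycle genes were occupied; these lists still passed, but the odds ratio of the ribosomal list was 5.17 in place of 20.4 and that of the pan-neuronal list 17.7 in place of 32.98. With the 500 strongest peaks alone the cell cycle list had an adjusted exact p of 0.10 and the collagens, below, an adjusted exact p of 1.

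The 2 lists that passed the test in the lower direction were chemoreceptors, genes of sensory neurons, and collagens of the cuticle. Of 1365 chemoreceptor genes 22 were occupied, or 1.61% (95% interval 1.01 to 2.43; adjusted exact p = 4.0e-75). The strongest were str-12 (220), sri-5 (189), srlf-7 (173) and srr-10 (161). Of 169 collagen genes 10 were occupied, or 5.92% (95% interval 2.87 to 10.6; adjusted exact p = 2.7e-04). One of these, col-71 (II, 3502680 to 3503039, signal 956, rank 36), was among the strong peaks of the whole list, and col-8, col-38 and col-55 had signals of 230, 216 and 176.

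**Figure D5:**
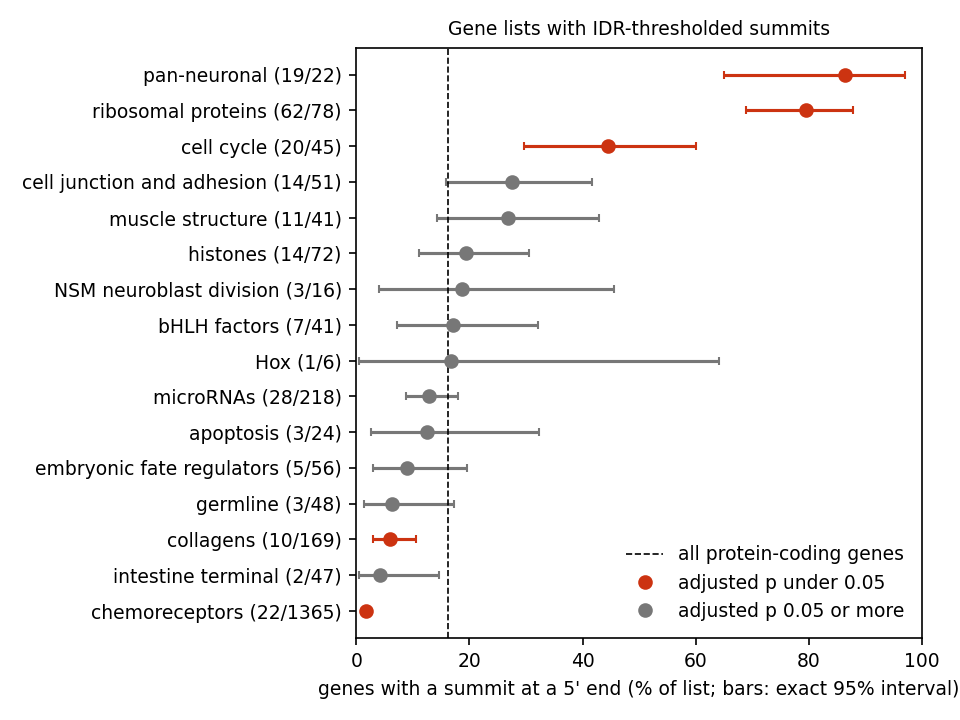
Share of genes in each list with a thresholded summit in the promoter window. Horizontal axis, percent of the list with exact 95% intervals; numbers beside each name are occupied genes over genes in the list; the dashed line marks all protein-coding genes, at 16.2%, while microRNAs were tested against other non-coding genes. Pan-neuronal genes (86.4%) and ribosomal protein genes (79.5%) lie to the right of the line, chemoreceptors (1.61%) and collagens (5.92%) to the left.

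The processes for which ces-1 is best known did not stand apart. Of 24 apoptosis genes 3 were occupied (adjusted exact p = 0.89), namely crn-1 (170), ced-5 (99.5) and ced-7 (67.5). Of 16 genes of NSM neuroblast division 3 were occupied (adjusted exact p = 0.89), pig-1, dnj-11 and grp-1, the last with a signal of 239. Of 41 genes for basic helix-loop-helix factors 7 were occupied (adjusted exact p = 0.89), with the strongest peaks at aha-1 (I, 10196875 to 10197378, signal 1018, rank 26), hif-1 (506), hlh-34 (220) and hlh-11 (138). Of 56 embryonic fate regulators 5 were occupied (adjusted exact p = 0.29), unc-42 and egl-27 (517) among them, with sys-1 at 81.2 and sox-2 at 79.8. Of the 6 Hox genes 1 was occupied, egl-5, with a signal of 80.1 (adjusted exact p = 1). The egl-5 peak had no match in the list of replicate 2, and with replicate 2 alone 0 Hox genes were occupied.

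The remaining lists did not pass the test either. Cell junction and adhesion genes were occupied at 14 of 51 (adjusted exact p = 0.082, unadjusted Fisher's exact p = 0.036), with zoo-1 at 780, unc-5 at 423, hmp-1 at 331.4 and fmi-1 at 331.3. With replicate 2 alone this list passed, with an adjusted exact p of 0.019. Muscle structure genes were occupied at 11 of 41 (adjusted exact p = 0.14), led by unc-112 (318), act-4 (223), act-2 (175) and dim-1 (124), and histone genes at 14 of 72 (adjusted exact p = 0.57). The histone pair his-67 and his-68 shared a summit with a signal of 315, and his-37 and his-61 had signals of 214 and 132; reads from near-identical histone copies cannot be placed with certainty. Germline genes were occupied at 3 of 48 (adjusted exact p = 0.13), mes-6 (456), nos-3 (340) and mes-2 (137), and terminal intestine genes at 2 of 47 (adjusted exact p = 0.071), elo-2 (191) and ifd-2 (72.0), the latter with no match in replicate 2. Of 218 microRNA genes 28 were occupied, or 12.8%, against 9.02% of other non-coding genes (adjusted exact p = 0.11), with mir-354 at 360, mir-5595 at 335, mir-5549 at 302 and mir-4932 at 273. The mir-5549 summit also lay in the promoter window of the translation factor gene eef-1A.1. Several lists near the threshold passed under other windows.

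The authors deposited each list on 2 genome builds. The thresholded list held 6290 peaks on ce11 and 6288 on ce10. Of the ce11 peaks, 6255, or 99.4%, had a ce10 peak on the same chromosome with the same width and summit offset and a signal within 0.1%.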

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

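The tests of explanations in this part were chosen after the patterns had been seen. The mitochondrial genome held 17 thresholded peaks, a signal outside the nuclear genome on which the report rests, at 1.23 per kb against 0.0626 per kb in the nucleus, with the best at rank 21.

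The libraries labelled eGFP-CES-1 had their strongest peaks at unc-42, no peak in the promoter window of ces-1, and no enrichment of CAGGTG. Extra copies of the unc-42 region stay open. The 20 kb on either side, beyond a gap of 5 kb, held 0 relaxed peaks each, as did 19.8% of such windows, against a 95th percentile of 16. The same sides of ces-1, a gene of which the labels give an integrated tagged copy, held only 3 and 8. Whether that copy takes in those sides was not examined. The number of weak peaks therefore cannot settle whether unc-42 had extra copies. Another candidate explanation that stays open is that the libraries hold another tagged factor, of the paired homeodomain class to which UNC-42 belongs: TAAT and ATTA 3 bp apart, a site such dimers favour, were 4.46 times as frequent at summits as in the flanks (127 summits against 31 and 26), and among the other spacings from 0 to 7 bp the highest ratio was 1.23. The site was found at only 2.02% of summits, a rate at which the 10 unc-42 summits are too few to test. Of these, 0 held it and 1 held CAGGTG. AATTGAAT, which can form the middle of the site, was at 8.43% of summits against 2.18% and 1.98% of flanks, and at 1 of the 10 unc-42 summits. It was also at the 1 thresholded summit within 5 kb of ces-1. With AATTGAAT at 529 summits and the full site at 127, most summits with AATTGAAT lacked the full site. The share of AATTGAAT was 11.1% in the strongest 20% of peaks and 6.46% in the weakest 20%. The share of the full site showed no such fall. By classes of 20% from the strongest to the weakest, it was 2.31%, 1.27%, 1.91%, 2.63% and 1.99%. Some motifs of other kinds were more common still, such as GAGAGA at 23.3% of summits. The site may therefore also come from other homeodomain factors at the same open regions. Binding of unc-42 by CES-1 was not tested, and neither was signal that does not depend on the tag.

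CAGGTG was 0.731 times as frequent at summits as in the flanks on average (bootstrap 95% interval 0.578 to 0.884). Base composition of the summits argues the other way as a cause: hexamers with the same composition had a median ratio of 1.18 (interval 1.08 to 1.24), although 7 of the 120 of them, CAGGTG included, were at or under its ratio. A loss of this site in open regions in general stays possible, since no list of another factor was analysed here, and no biological explanation was tested. Coding exons held 2.53% of summits against 24.3% when shifted. Flanks were not matched to summits for coding sequence, and the comparison by base composition does not remove that difference.

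The X chromosome held more peaks than its length gives. More sequence outside coding exons on X does not account for the whole excess. The X share of peaks there was still 1.20 times the X share of such sequence (interval 1.14 to 1.26), against 1.29 times by length. A higher background on X in these libraries stays open for part of the excess: among the weakest 10000 relaxed peaks the X share was 19.9% (interval 19.1 to 20.7) against 17.7% of the length, below the 22.7% of the thresholded list. The share was 26.1% between the end of the thresholded list and rank 10000, and 21.2% in the strongest 20% of peaks. No biological explanation was tested, as the design holds a single group.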

How the results depend on the processing

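Of 186 recomputed values, 167 counted as kept, 3 lost their call, 8 gained one, 2 turned and 6 moved. Kept values stayed on their side of the threshold, within their error or a set margin, or unchanged. A gene list counted as turned only if it passed in at least 1 of the 2 settings compared. Some lists that passed in neither therefore changed direction among those kept. For example, the odds ratio of basic helix-loop-helix genes was 1.07 in the main setting and 0.762 with 2000 bp upstream to 500 bp downstream. The cause was not tested except where stated. A stricter IDR of 0.01 was not run, since no IDR value per peak was at hand. Merging summits within 100 bp removed no peak, so its values, counted among those kept, could not change and say nothing of stability. The same holds for named genes without a summit in the main promoter window when the narrower window inside it was used. With the 500 strongest peaks, the X ratio was 1.18 (exact binomial p = 0.067), the build match 99.8%, the number of lists past the threshold 2, and the pan-neuronal odds ratio 0, with 0 genes occupied; fewer peaks lower the number of lists a test can call. With peaks given to the nearest 5′ end alone, 6 lists passed, with 30 ribosomal, 15 pan-neuronal, 12 cell cycle, 14 chemoreceptor and 3 collagen genes occupied. With 2000 bp upstream to 500 bp downstream, 9 lists passed. At a summit distance of 200 bp the signal correlation was 0.793. With a 25 bp window the signal difference at CAGGTG was 0.190 (permutation p = 0.99). No paired analysis was possible because there is 1 group. Without either replicate in turn, the promoter share was 44.7% to 44.9%, the X ratio 1.286 to 1.291, the CAGGTG difference −0.797 to −0.749 points, the signal difference −9.72 to −6.49 on the lower signal scale of a single replicate, not comparable in size with the pooled −13.2, and 5 to 6 lists passed. Junction and adhesion genes passed in 3 of 7 alternatives, microRNAs in 2, intestine genes in 2 and muscle genes in 1. Read depth is unknown, so what it limits was not measured.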

Other observations

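The tests in this part were chosen after the data had been seen, as were its gene lists and motifs. In the list tests, as above, the number of 5′ ends and expression in embryos were not adjusted for. Besides ribosomal proteins, other genes of basic cell machinery were occupied more often than the 16.2% of all protein-coding genes, by Fisher's exact test with adjustment over 14 added lists. Proteasome subunits had a summit at 21 of 33 genes (adjusted exact p = 3.9e-09), led by rpn-3 with a signal of 651. Translation factors were occupied at 20 of 31 (adjusted exact p = 5.5e-09), splicing factors at 16 of 28 (adjusted exact p = 1.8e-06), mitochondrial ribosomal proteins at 30 of 70 (adjusted exact p = 2.6e-07), aminoacyl-tRNA synthetases at 13 of 32 (adjusted exact p = 0.0011) and Rab GTPases, which steer vesicle traffic, at 11 of 20 (adjusted exact p = 1.2e-04). Genes named unc for uncoordinated movement, many of them neuronal, were occupied at 48 of 94 (adjusted exact p = 7.3e-14). This list shares genes with lists fixed in advance, such as unc-42, unc-18 and unc-104, so it is not independent of them. Of 10 glutamate receptor genes 6 were occupied (adjusted exact p = 0.0024), with glr-1 at a signal of 341 and glr-5 at 267.

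Of the added lists, 6 were occupied less often than other genes. F-box genes had a summit at 15 of 328 (adjusted exact p = 3.1e-10), C-type lectins at 6 of 240 (adjusted exact p = 7.2e-11), nuclear hormone receptors at 23 of 269 (adjusted exact p = 4.4e-04) and neuropeptide genes at 10 of 140 (adjusted exact p = 0.0027). Cytochrome P450 genes had 0 of 74 (adjusted exact p = 6.6e-06) and major sperm protein genes 0 of 31 (adjusted exact p = 0.0063), which allow shares of up to 4.86% and 11.2%.

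Sequence at the summits was far from that of the flanks. Against the flank with more, 637 of 2080 hexamers were more frequent at summits after adjustment and 582 less, and since that flank makes the test strict for a rise and lenient for a fall, 475 were less frequent against both flanks, in a setting where summits had a GC content of 41% and flanks of 34.87% and 34.99%. Among the hexamers more frequent at summits, GAGAGA had the lowest p, at 1461 summits, or 23.3%, against 326 and 323 flanks (exact McNemar adjusted p = 1.7e-188 over all hexamers). The longer AGACGCAG stood at 439 summits against 37 and 32 flanks, and its share by classes of 20% of peaks, from the strongest to the weakest, was 8.92%, 10.04%, 6.93%, 5.34% and 3.75%. AATTGAAT, which can form the middle of TAAT and ATTA 3 bp apart, stood at 529 summits against 137 and 124 flanks, and GCAAACAC at 187 against 22 and 17. Among E-boxes, CAAGTG was at 401 summits against 246 and 242 flanks (exact McNemar adjusted p = 3.5e-09 over 10 E-boxes), CACATG at 284 against 187 and 180 and CAATTG at 376 against 267 and 257 (both adjusted exact p = 3.2e-05), and CAACTG at 226 against 293 and 280 (adjusted exact p = 0.0073; unadjusted exact p = 0.016 against the flank with fewer).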
